A study of Mus musculus with 4 samples.

How the data were processed

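Poly(A)-enriched RNA libraries were made from freshly isolated islets of 30-week-old C57BL/6 mice, with RNA extracted on RNeasy Plus Mini columns and Illumina sequencing, per the labels' protocols. The labels give 4 samples, 2 Ggcx flox/flox and 2 Ggcx flox/flox with Pdx1-Cre, each a pool of islets from 2 mice. The submitters' processing notes name CASAVA 1.4, STAR 2.5.1b, featureCounts 1.6.0, DESeq2 1.22.2 and the GRCm38 build, without their roles. The annotation and the strand setting were not given in the sources used here.

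One table of 55487 genes was used. The authors deposited a signal value per gene and library, a read count normalized to library size per the file name and headers. Dividing each column by the value of 1 read gave whole reads for 100% of values, within 0.01 of a read, so reads and depth per library were recovered. The authors also deposited a log2 fold change (control over knockout, by its sign against the library values) with its standard error, a p-value and an adjusted p-value per gene. These were used only to count calls. The knockout columns were matched to samples by name. The control columns carry the numbers 2 and 3 while the labels number these samples otherwise, so they were matched to the group and not to a sample. No column of another sample was found (0).

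Total reads per library ranged from 47624630 to 51756221, so counting error is small for all but the lowest genes, and the spread between pools sets the precision. The labels list the replicates as separate samples, each of 2 mice, so each was counted as its own replicate. Chi-square over degrees of freedom was 10.1 for the controls and 9.85 for the knockouts over genes with 20 or more reads in the pair, which argues only against 1 library deposited under both names. The p-values combine each gene's spread between 2 pools per genotype with a spread borrowed from the other genes, which carries more weight. An exact permutation test of 2 against 2 cannot go below p = 0.333 (two-sided), so tests borrowing spread across genes were used.

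Genes with a value of at least 10 in at least 2 of the 4 libraries were tested (16589) with limma 3.58.1 in R 4.3.3 on log2(value + 1), with lmFit and eBayes with a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. The pseudocount of 1 understates the change of low genes. The prior held 6.85 degrees of freedom beside 2 residual ones. Because the values are normalized, a count model was an alternative only: edgeR 4.0.16 (quasi-likelihood, TMM) called 57 genes higher and 71 lower on the recovered reads, and DESeq2 1.42.0 called 120 and 202, with 3217 adjusted p-values left NA.

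The gene lists, the rule for named genes and the tests were fixed before the data were examined. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Sex-linked genes were set beforehand to be described only and not tested as a list. Where 2 rows shared a symbol, the one with the higher mean was used. Named genes were Ggcx, then in each direction the 12 largest log2 fold changes with adjusted p under 0.05, a mean of at least 50, group ranges that do not overlap and no predicted or clone name. Each list added up to 4 called members in order of p, or its 2 most abundant members when none was called. Ins1, Ins2, Mafa, Ucn3, Slc2a2, Gcg, Sst, Ppy and Asph were always named. Some genes that the rule names are not reported here. Coordinates are from GENCODE release M21 on GRCm38, which holds 99.4% of the gene identifiers of the table. Exons of 12 of the 83 named genes overlap those of another tested gene.

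The alternatives were pseudocounts of 0.5 and 5, no filter on low values, a filter at 50, scaling to a common total or a common upper quartile, limma without the trend or with robust empirical Bayes, each library left out in turn, and the count tests. The steps were tested on simulated data for the comparison of knockout with control, with 55487 genes drawn in each of 5 simulations from the real means, depths and trended dispersions. Of 100 genes changed 1.5-fold, 68.6% were recovered on average, and of 100 changed 2-fold, 82.4%. Unchanged genes made up 5.13% of calls. The simulation gives all genes of one abundance the same dispersion and draws genes independently, so real recovery can be lower. The share of unchanged genes among the real calls can be higher, and the simulation does not measure it.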

Results

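RNA was sequenced from freshly isolated pancreatic islets, the hormone-secreting clusters of the pancreas, of 30-week-old C57BL/6 mice. Of 4 libraries, 2 came from Ggcx flox/flox mice, which keep a working Ggcx gene and carry no Cre (control), and 2 from Ggcx flox/flox mice with the Pdx1-Cre transgene (knockout). Pdx1-Cre drives recombination in the pancreatic lineage. Each library pooled the islets of 2 mice, so n = 2 pools per genotype. The libraries held 48389100 and 50524121 reads assigned to genes in control islets, and 47624630 and 51756221 in knockout islets. The control libraries are named here by their numbers in the deposited table (columns 2 and 3), which do not match the numbering of the control samples in the labels. Values are normalized read counts, and log2 fold changes are knockout over control on the log2(value + 1) scale, given with their standard errors. No library carried Cre together with intact Ggcx, so the comparison covers the transgene and the loss of Ggcx together.

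The first comparison asked how much Ggcx transcript was left in knockout islets. Ggcx (ENSMUSG00000053460; GRCm38 chromosome 6, 72414308 to 72430712, plus strand) encodes gamma-glutamyl carboxylase, the vitamin K-dependent enzyme that converts glutamate residues of its substrate proteins to gamma-carboxyglutamate. Its normalized count was 3971 and 3981 in the control libraries and 234.2 and 643.4 in the knockout libraries. The mean fell from 3976 ± 7.03 (SD, n = 2) to 439 ± 289 (SD, n = 2), with a log2 fold change of -3.35 ± 0.35 and a limma adjusted p of 0.0163. Knockout replicates 1 and 2 kept 5.89% and 16.2% of the control mean. The gene total does not separate the floxed exons from the rest of the transcript, and it includes islet cells in which Cre was not active. The call ended with no filter on low values, without the mean-variance trend and with robust empirical Bayes, where the log2 fold change was still -3.35.

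The second comparison asked which other transcripts differed between the genotypes. Of 16589 tested genes, 41 rose and 62 fell in knockout islets at an adjusted p under 0.05. Most of these changes were modest: 10 of the genes that rose and 4 of those that fell changed by 1 or more on the log2 scale. Zfp423 rose far more than any other gene, followed by C7, Bcat1, Cldn2 and Dcn among the genes chosen for size. After Ggcx, the genes chosen for size that fell the most were Mlph, Fhl2, Ffar2 and Rsph4a.

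Zfp423 (ENSMUSG00000045333; GRCm38 chromosome 8, 87661810 to 87959595, minus strand) encodes a zinc finger transcription factor with a role in adipocyte commitment. It was near the low end of the measured range in control islets, at 22.5 and 27.3 normalized counts, and stood at 2316 and 5723 in knockout islets. The mean was 24.9 ± 3.39 (SD, n = 2) in controls and 4019 ± 2409 (SD, n = 2) in knockouts, a 141-fold rise with a log2 fold change of 7.14 ± 0.33 and a limma adjusted p of 9.95e-05. The rise was 222-fold without knockout replicate 1 and 89.9-fold without knockout replicate 2. The call ended without the mean-variance trend and with robust empirical Bayes.

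Serpina7, which encodes thyroxine-binding globulin, rose from 1285 ± 148 to 2857 ± 146 (SD, n = 2 each), with a log2 fold change of 1.16 ± 0.08 and a limma adjusted p of 0.0012. Ghrl, the ghrelin gene, rose from 85.2 ± 2.06 to 192 ± 26.3 (SD, n = 2 each), or 2.23-fold. Complement component C7 rose from 36.1 ± 12.5 to 136 ± 32.6, and the cytosolic branched-chain aminotransferase Bcat1 rose from 38.5 ± 7.65 to 113 ± 20.7 (SD, n = 2 each). The tight junction gene Cldn2 rose 2.52-fold, the proteoglycan gene Dcn 2.45-fold, and Gdf10, a member of the TGF-beta superfamily, 2.19-fold. Dcn is also a stellate cell and fibroblast marker, and these markers were higher in the same islets (median 0.48). Its rise is not separated from that of the cell type, and whether C7 or the other rising genes follow a cell type was not tested. Smaller rises were measured for Iqgap2 (1.86-fold), Tmem179 (1.70-fold), Smoc1 (1.67-fold) and Fam167a (1.67-fold). Exons of Ghrl overlap those of a gene on the opposite strand, and the strand setting of the counting was not given in the sources used here.

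Mlph, which encodes the melanophilin adaptor that links Rab27a to myosin Va, fell from 791 ± 13.5 to 244 ± 93.2 (SD, n = 2 each), with a log2 fold change of -1.75 ± 0.21. Ffar2, a receptor for short-chain fatty acids, fell from 1215 ± 7.11 to 593 ± 31.5 (SD, n = 2 each), with a log2 fold change of -1.04 ± 0.07 and a limma adjusted p of 0.0012. The LIM-domain gene Fhl2 fell from 616 ± 117 to 279 ± 22.0, and the ciliary radial spoke gene Rsph4a fell from 2141 ± 333 to 1078 ± 111 (SD, n = 2 each). Relb, Scel, Itpkc, Ocln, Eppk1, Try4 and Adamts9 fell as well, with log2 fold changes between -0.87 for Relb and -0.73 for Adamts9. Itpkc shares exon positions with a gene on the opposite strand, and Try4 belongs to the trypsinogen family, whose members can share reads.

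**Figure D1:**
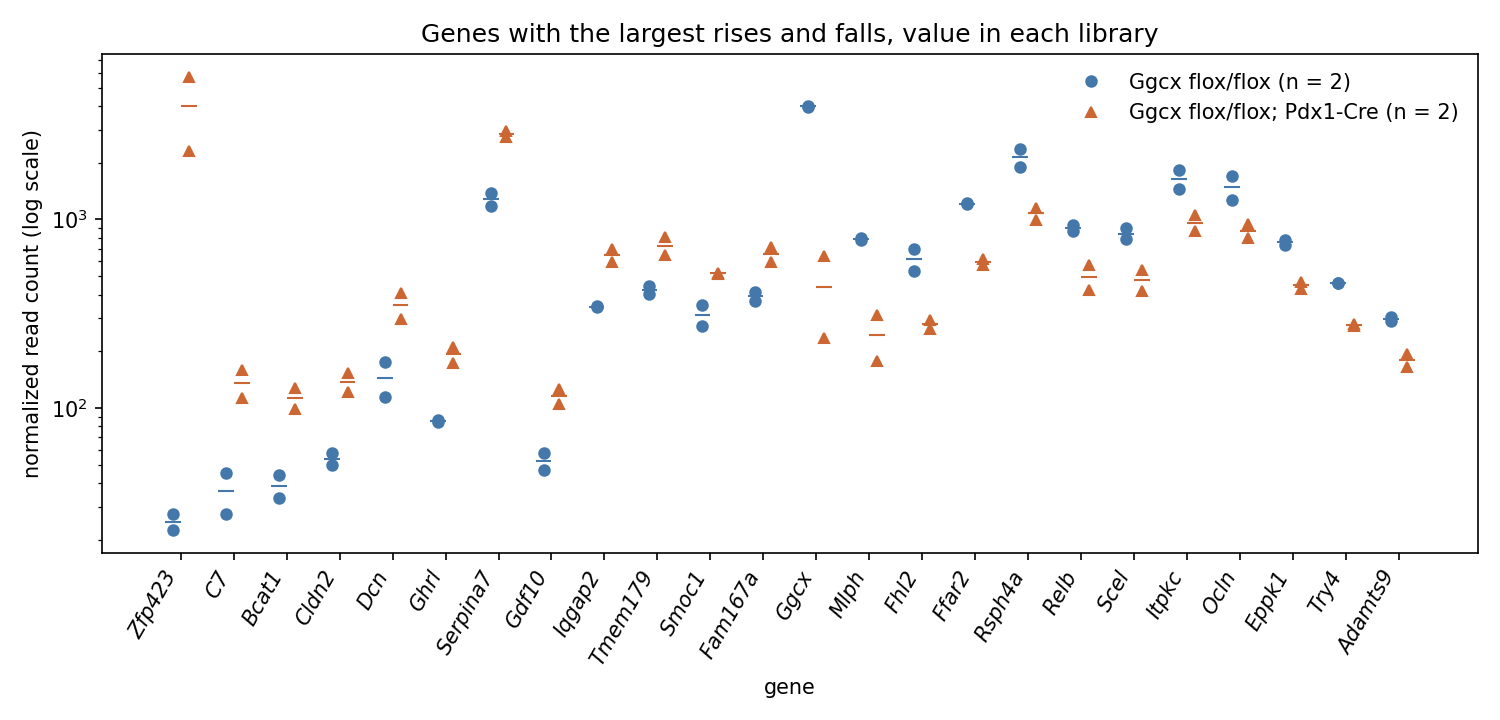
Normalized read count (log scale) in each library of the 12 genes with the largest rises and the 12 with the largest falls. These were chosen among genes with a limma adjusted p under 0.05, a mean of at least 50, group ranges that do not overlap and no predicted or clone name. Circles are control libraries, triangles knockout libraries, and short bars group means (n = 2). Zfp423 stands at 22.5 and 27.3 in controls and at 2316 and 5723 in knockouts, and Ggcx at 3971 and 3981 in controls and at 234.2 and 643.4 in knockouts.

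The counts of called genes differed between settings of the test. No gene passed without the mean-variance trend of limma (1841 at an unadjusted p under 0.05), 1 rose and 1 fell with no filter on low values, 85 rose and 124 fell with robust empirical Bayes, and DESeq2 on the recovered reads called 120 higher and 202 lower. Higher genes made up 39.8% of the calls, and 50.9% after scaling to a common upper quartile (57 higher, 55 lower). Of the 35 named genes that passed, only Zfp423 and Ffar2 stayed called with no filter, and none without the trend. Without control column 3 the calls of Bcat1, Dcn, Smoc1, Itpkc, Ocln, Adamts9, Ddit3, Birc3 and Rbp4 were lost. Those of Gdf10, Adamts9, Ddit3, Birc3 and Rbp4 were lost without knockout replicate 1, that of Gdf10 without control column 2, and that of Rbp4 without knockout replicate 2. A filter at 50 ended the calls of Dcn, Gdf10, Smoc1, Itpkc, Ocln, Adamts9, Ddit3, Trp53inp1, Birc3 and Rbp4, and robust empirical Bayes those of Ggcx, Zfp423, Dcn, Mlph, Itpkc, Ocln and Trp53inp1. Scaling to a common total ended that of Rbp4 and a common upper quartile that of Birc3.

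Fixed gene lists were used to ask which functions and cell types moved as groups. Of 30 lists tested with camera, 9 were higher and 4 lower in knockout islets. All 13 calls were made with the preset inter-gene correlation of 0.01. With a correlation estimated from the data no list was called, and none had an unadjusted p under 0.05. That form of camera takes its p-values on the 2 residual degrees of freedom, so it had little power. Even the acinar list, at a camera p of 3.56e-17 with the preset correlation, came to 0.164. The delta and PP cell lists lost their call at estimated correlations of -0.065 and 0.0039, which are below the preset one. Losing a call under this alternative therefore neither removes nor backs that call. Fry called no list in one direction either, with 2 at an unadjusted p under 0.05. Its mixed test, which asks whether members change in either direction, passed the adjusted threshold for 14 lists. Besides called lists, these included lists that camera did not call, such as Gla proteins (fry mixed adjusted p = 0.0159) and the integrated stress response (0.0325). The mixed test does not compare a list with the other genes. Of all 16589 tested genes, 2336 had an unadjusted limma p under 0.05, so a pass does not set a list apart.

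In the vitamin K cycle, Ggcx fell and the other 6 measured genes did not pass the test (2 of all 7, Ggcx included, fell when adjusted over the list alone; camera adjusted p = 0.304). The list was called lower without knockout replicate 2 (camera adjusted p = 0.00246), but it holds Ggcx itself, at -4.08 in that fit, and its median there was -0.02; the other members were not tested without Ggcx. None of 10 measured Gla protein genes, which encode substrates of the carboxylase, passed the test (1 rose when adjusted over the list alone; camera adjusted p = 0.104). Asph, aspartate beta-hydroxylase, stood at 3416 ± 273 in controls and 3391 ± 15.8 in knockouts, and Prrg2 at 1290 ± 78.8 and 1424 ± 72.8 (SD, n = 2 each).

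Among 31 measured genes of beta-cell identity, Gpr119, a receptor for lipid amides, rose 1.48-fold and 30 did not pass the test (Gpr119 alone rose when adjusted over the list alone; camera adjusted p = 0.104). The list was called lower without control column 2 (camera adjusted p = 0.0172) and without knockout replicate 2 (0.0151). Insulin transcripts Ins1 and Ins2 together took 18.6% ± 0.66 of reads in controls and 19.4% ± 0.47 in knockouts (SD, n = 2 each). The log2 fold change was 0.12 ± 0.16 for Ins1, 0.04 ± 0.20 for Ins2, -0.13 ± 0.12 for Mafa, -0.06 ± 0.05 for Ucn3 and -0.17 ± 0.05 for the glucose transporter Slc2a2, none past the threshold. In stimulus-secretion coupling, 0 of 30 genes passed the test (2 fell when adjusted over the list alone; camera adjusted p = 0.851), with Chga at -0.06 ± 0.09 and Scg2 at 0.06 ± 0.11. Its median and mean were above 0 while camera, which compares a list with the other genes, gave the direction down.

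Disallowed and dedifferentiation genes, which mature beta cells normally keep low, were higher as a list, with a median log2 fold change of 0.27 (camera adjusted p = 5.35e-07; adjusted p = 0.488 with an estimated correlation). Serpina7 rose and the other 26 of 27 genes did not pass the test (8 of all 27, Serpina7 included, rose when adjusted over the list alone). The member Pdgfra also stands in the stellate cell list, whose markers were higher in the same islets, with a median of 0.48. Sox9 also stands in the duct cell list, which was not called. The RNA came from whole islets, in which alpha, delta and PP cell markers were also higher, so the rise of this list is not assigned to beta cells. Of the lactogen-responsive islet genes, 0 of 16 passed the test (0 when adjusted over the list alone; camera adjusted p = 0.104), with Chgb at 0.14 ± 0.06 and Prlr at -0.02 ± 0.08.

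In the integrated stress response, Trib3 fell from 1455 ± 36.4 to 1078 ± 37.8 and Ddit3, which encodes CHOP, fell from 10669 ± 494 to 8155 ± 671 (SD, n = 2 each). The other 25 of 27 genes did not pass the test (of all 27, 2 rose and 5 fell, Trib3 and Ddit3 included, when adjusted over the list alone; camera adjusted p = 0.830). Ddit3 exons overlap 2 genes on the opposite strand. ER chaperones were lower as a list (median -0.05; camera adjusted p = 0.0442; adjusted p = 0.628 with an estimated correlation), but none of 27 passed the test (3 fell when adjusted over the list alone). Hspa5 stood at -0.11 ± 0.08 and Hsp90b1 at -0.05 ± 0.06. The call was lost without control column 2 (camera adjusted p = 0.860), without knockout replicate 2 (0.104), with a filter at 50 (0.0724) and with a common upper quartile (0.0722). In ER calcium handling none of 25 genes passed (0 when adjusted over the list alone; camera adjusted p = 0.559), with the calcium pumps Atp2a2 at -0.23 ± 0.06 and Atp2a3 at -0.04 ± 0.05. Its median and mean were above 0 and its camera direction down.

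In the NF-kB and inflammatory list, Nfkbia, Tnfaip3, Relb and Birc3 fell and 15 of 19 genes did not pass the test (of all 19, 1 rose and 5 fell when adjusted over the list alone). Nfkbia and Tnfaip3 encode inhibitors of NF-kB signalling, Relb a subunit of the factor, and Birc3 an inhibitor of apoptosis. Nfkbia fell from 7503 ± 145 to 5371 ± 182 and Tnfaip3 from 4266 ± 207 to 2900 ± 309 (SD, n = 2 each). The list was lower (median -0.07; camera adjusted p = 0.0365; adjusted p = 0.618 with an estimated correlation). That call was lost without control column 2 (camera adjusted p = 0.569) and with no filter on low values (0.146). Acinar markers, described below with the cell types, were lower in the same islets, with a median of -0.71. The interferon list was higher (median 0.15; camera adjusted p = 0.000764; adjusted p = 0.658 with an estimated correlation), with none of 32 genes past the test (0 when adjusted over the list alone) and H2-K1 at 0.11 ± 0.05 and H2-D1 at 0.11 ± 0.05. It was lost without control column 3 (camera adjusted p = 0.730) and without knockout replicate 1 (0.129).

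In cholesterol synthesis, Hmgcs1, which makes HMG-CoA, fell from 7275 ± 416 to 5024 ± 152 (SD, n = 2 each), and 24 of 25 genes did not pass the test (of all 25, 4 fell when adjusted over the list alone). The list was lower (median -0.05; camera adjusted p = 0.0103; adjusted p = 0.590 with an estimated correlation), and the call was lost without control column 3 (camera adjusted p = 0.158). Nuclear-encoded oxidative phosphorylation genes were slightly higher as a list, with 43 of 46 log2 fold changes above 0 and a median of 0.06 (camera adjusted p = 2.69e-05; adjusted p = 0.488 with an estimated correlation). None passed the test singly (2 rose when adjusted over the list alone), with Sdha at -0.02 ± 0.05.

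The p53 and apoptosis list was not called (camera adjusted p = 0.0503). Within it Trp53inp1 fell from 11890 ± 1562 to 8274 ± 446 (SD, n = 2 each), and 23 of 24 genes did not pass (of all 24, 5 rose and 1 fell when adjusted over the list alone). The list was called higher with a pseudocount of 5 (0.0499), a common total (0.0479), without control column 2 (0.0367) and without knockout replicate 2 (0.00579). No member of the following lists passed the test, and camera called none of them with all libraries. The camera adjusted p was 0.830 for the cell cycle, whose median and mean were above 0 with the direction down, 0.398 for glycolysis and 0.347 for the NRF2 response. It was 0.203 for immediate early genes, which were called lower without knockout replicate 2 (0.000175) and had the direction up without knockout replicate 1 (0.604), and 0.559 for mitochondrially encoded mRNAs. Adjusted over the list alone, 1 NRF2 gene fell, 1 immediate early gene rose and 3 fell, and none passed in the other 3 lists. Log2 fold changes of their most abundant members were -0.10 ± 0.07 for Pcna, -0.10 ± 0.10 for Mcm2, -0.06 ± 0.05 for Pkm, 0.05 ± 0.05 for Aldoa, 0.03 ± 0.05 for Ftl1 and 0.05 ± 0.05 for Fth1. They were 0.06 ± 0.08 for Jun, -0.15 ± 0.08 for Fosb, 0.04 ± 0.08 for mt-Co1 and -0.01 ± 0.07 for mt-Cytb.

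The alpha, delta and PP cell lists were called higher with the preset correlation and none of them with an estimated one, and most of their members did not pass the test. In the alpha cell list, the glutamate receptor gene Gria3 rose from 834 ± 29.7 to 1158 ± 21.2 (SD, n = 2 each). In that list 9 of 11 genes did not pass (5 of all 11 rose when adjusted over the list alone; median 0.26; camera adjusted p = 1.12e-06; adjusted p = 0.488 with an estimated correlation). The alpha median was 0.15 without control column 2, 0.41 without control column 3, 0.13 without knockout replicate 1 and 0.45 without knockout replicate 2. Glucagon (Gcg) stood at 0.26 ± 0.14 (0.13 without knockout replicate 1 and 0.39 without knockout replicate 2), and took 2.40% ± 0.26 of reads in controls and 2.87% ± 0.38 in knockouts (SD, n = 2 each). In the delta cell list, Rbp4 rose from 5266 ± 65.1 to 6356 ± 40.7 (SD, n = 2 each) and 7 of 8 did not pass (1 of all 8 rose when adjusted over the list alone), with Sst at 0.11 ± 0.07. The list was higher (median 0.11; camera adjusted p = 0.0397; adjusted p = 0.488 with an estimated correlation), a call lost without control column 2, control column 3 or knockout replicate 2 (camera adjusted p = 0.0911, 0.0801 and 0.0930). None of 4 PP cell genes passed (2 rose when adjusted over the list alone; median 0.27; camera adjusted p = 0.0103; adjusted p = 0.488 with an estimated correlation). Ppy stood at 0.45 ± 0.19 (0.098 without control column 3 and 0.80 without control column 2) and Pyy at 0.21 ± 0.08, and the list's call was lost without control column 3 (camera adjusted p = 0.0590).

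Acinar cell markers, the digestive enzyme genes of the exocrine pancreas, were lower, with 25 of 26 log2 fold changes below 0 and a median of -0.71 (camera adjusted p = 1.07e-15; adjusted p = 0.488 with an estimated correlation). Try4 fell from 460.8 ± 0.019 to 277 ± 4.73 (SD, n = 2 each), and the other 25 of 26 genes did not pass the test (21 of all 26 fell when adjusted over the list alone). The acinar median was -0.34 without knockout replicate 1 and -1.07 without knockout replicate 2. Stellate cell and fibroblast markers were higher (median 0.48; camera adjusted p = 4.50e-07; adjusted p = 0.488 with an estimated correlation). Dcn rose from 144 ± 43.0 to 352 ± 79.0 (SD, n = 2 each), and 16 of 17 did not pass (7 of all 17 rose when adjusted over the list alone). The stellate median was 0.24 without knockout replicate 1 and 0.30 without control column 3. Lymphocyte markers were higher (5 of 5 above 0, none past the test, 1 when adjusted over the list alone; camera adjusted p = 0.0103; adjusted p = 0.488 with an estimated correlation). Of 18 lymphocyte markers 5 were tested, with a median of 0.57. Ighm stood at 1.85 ± 0.47 (0.92 without knockout replicate 1 and 2.79 without knockout replicate 2) and Cd79a at 0.18 ± 0.15. Leaving out control column 3 ended the call (camera adjusted p = 0.0609). Schwann cell and neuron markers were higher (10 of 10 above 0, none past the test, 0 when adjusted over the list alone; camera adjusted p = 0.00327; adjusted p = 0.488 with an estimated correlation). Their median was 0.34, with Prnp at 0.03 ± 0.05. The call was lost with a filter at 50 (camera adjusted p = 0.0508) and without control column 2.

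Other cell types were not called with all libraries. The camera adjusted p was 0.389 for duct cells (1 rose and 1 fell when adjusted over the list alone), 0.0503 for endothelial cells (1 rose), 0.559 for macrophages and dendritic cells (0) and 0.0503 for erythroid cells (1 rose). The endothelial list was called higher with a common upper quartile (0.0439), without control column 2 (4.17e-05) and without knockout replicate 1 (0.0228). The erythroid list was called higher with a pseudocount of 5 (0.0493), a common total (0.0427) and without knockout replicate 1 (0.00102). Log2 fold changes were -0.22 ± 0.06 for Krt18, -0.05 ± 0.05 for Krt7, 0.11 ± 0.10 for Plvap, 0.03 ± 0.07 for Flt1, -0.05 ± 0.09 for Cd74, -0.09 ± 0.08 for H2-Aa, 0.36 ± 0.11 for Hbb-bs and 0.30 ± 0.21 for Hba-a1. Adipocyte markers could not be tested as a list, since 1 member was measured, Aqp7, at -0.31 ± 0.27. The Y-linked genes Ddx3y (-0.12 ± 0.05) and Uty (-0.01 ± 0.06) were expressed in all 4 libraries, and Xist was at or below 2.04 normalized counts in each.

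**Figure D2:**
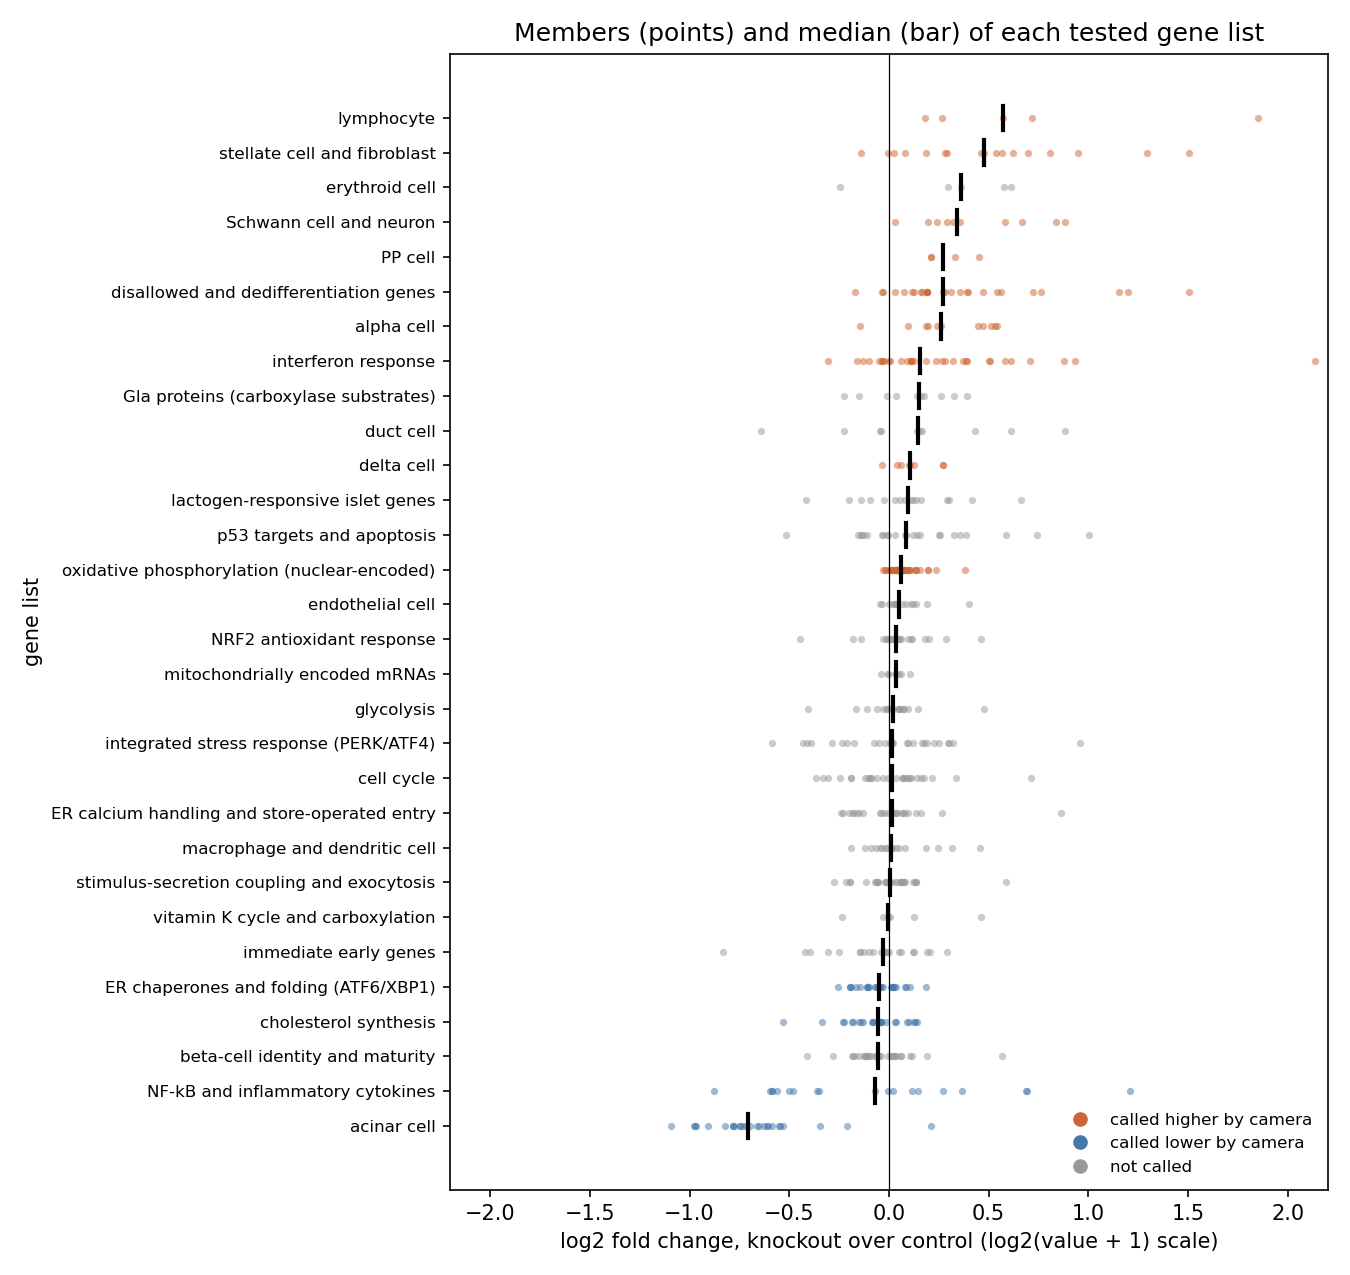
Log2 fold change, knockout over control, of each measured member (points) and the median (black bars) of the 30 tested gene lists; orange lists were called higher, blue lists lower and grey lists not called by camera with the preset correlation. The acinar list lies lowest, at a median of -0.71, and 1 member, Ggcx at -3.35, lies outside the axis.

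The authors' deposited table gives 111 genes higher and 203 lower in knockout islets at its adjusted p under 0.05. Of the 103 genes called here, 102 were also called in the authors' deposited table.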

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

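All alternatives reported here were planned before the data were examined. No paired analysis was possible because the control columns carry numbers that do not match the labels, so the planned fit with the replicate number as a block was not run. The 41 higher and 62 lower genes became 1 and 1 with no filter on low values, 19 and 32 with a filter at 50, 0 and 0 without the mean-variance trend (1841 at an unadjusted p under 0.05), 85 and 124 with robust empirical Bayes, and 120 and 202 with DESeq2. Removing low genes from the test, or adding them, changes the number of genes adjusted for and the fitted trend; which of these moved the counts was not tested, nor was the cause for the other settings. Of the 103 called genes, 103 kept the call with edgeR, 102 with DESeq2, 92 with robust empirical Bayes, 51 with a filter at 50, 2 with no filter and 0 without the trend, and all 103 kept their sign, or 102 of 102 tested with a filter at 50. Scaling to a common upper quartile raised the share of higher genes from 39.8% to 50.9%.

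With 1 library left out, the lone library of its group is assumed to vary like the other group. Higher genes then ranged from 58 to 207 and lower genes from 49 to 241. Without control column 2 there were 207 and 241, without knockout replicate 1 there were 72 and 98, and without knockout replicate 2 there were 101 and 148. Of the 103 calls, 101 were kept without control column 2, 52 without control column 3, 73 without knockout replicate 1 and 87 without knockout replicate 2. The log2 fold change of Ggcx ranged from -4.08 (without knockout replicate 2) to -2.63 (without knockout replicate 1) and stayed called. It was -3.35 with no filter, without the trend and with robust empirical Bayes, and not called in any of these (adjusted p 0.217, 0.329 and 0.294, against a range of 1.18e-14 to 0.329 over its alternatives); the cause was not tested. The 9 higher and 4 lower lists became 0 and 0 with an estimated correlation and 0 and 0 with fry. They ranged from 5 to 10 and from 3 to 6 with 1 library left out, the 5 without control column 3. Of the lists not called, 6 were called in at least 1 setting. The disallowed, oxidative phosphorylation, alpha cell, acinar and stellate lists kept their call in the 10 settings with the preset correlation that change what camera is given, which the trend and robust settings do not. Medians of other called lists also moved by over 1.5 times with 1 library left out. Without control column 2, ER chaperones came to 0.014, cholesterol synthesis to -0.093 and interferon to 0.34. Without control column 3, ER chaperones came to -0.090, oxidative phosphorylation to 0.038, interferon to 0.068, NF-kB to -0.16, PP cells to 0.14, lymphocytes to 0.34 and Schwann cells to 0.68. Without knockout replicate 1, ER chaperones came to -0.083, cholesterol synthesis to -0.030 and lymphocytes to 0.32, and without knockout replicate 2 cholesterol synthesis came to -0.086, interferon to 0.26 and NF-kB to -0.12.

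Of 1161 values of named genes under alternatives, 1034 kept direction and side of the threshold, 103 lost the call, 5 gained one and 19 changed sign, none of these past the threshold on either side. The gained calls included Atp2a2 (-0.23) with DESeq2, Ppy (0.80) and Mafa (-0.36) without control column 2, and Ighm (2.79) without knockout replicate 2, while Ppy came to 0.098 without control column 3 and Ighm to 0.92 without knockout replicate 1. With a common upper quartile Asph came to 0.011, mt-Cytb to 0.014 and Uty to 0.0053. With 1 library left out, the ranges that cross 0 were -0.090 to 0.074 for Asph, -0.070 to 0.19 for Scg2, -0.023 to 0.078 for Ftl1, -0.15 to 0.10 for Prlr, -0.022 to 0.15 for Jun, -0.029 to 0.019 for mt-Cytb, -0.052 to 0.025 for Uty, -0.030 to 0.25 for Plvap, -0.065 to 0.12 for Flt1, -0.17 to 0.076 for Cd74, -0.19 to 0.019 for H2-Aa and -0.36 to 0.10 for Mafa. At 47624630 reads or more per library, depth limits only the lowest genes, such as Zfp423 in controls.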

Other observations

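All tests in this part were chosen after the results were seen, as were the genes first named here. No list of clock genes was fixed or tested. Per2 (-0.54 ± 0.08), Dbp (-0.44 ± 0.07) and Nr1d1 (-0.40 ± 0.07) fell past the threshold, each with n = 2 per genotype. Per1 (-0.43 ± 0.08) and Per3 (-0.16 ± 0.09) did not pass it. All 10 clock output and repressor genes looked at were below 0, with a median of -0.37, and 3 of them passed. The activators stood at -0.06 ± 0.08 for Arntl, -0.09 ± 0.06 for Clock and 0.03 ± 0.13 for Npas2. The metallothionein gene Mt2 fell (-0.50 ± 0.09), and Mt1 stood at -0.39 ± 0.08, not past the threshold.

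No test of a group was run for the following genes. Edn3, which encodes endothelin 3, rose by a log2 fold change of 0.57 ± 0.09, C1s1 by 0.69 ± 0.11 and Serping1 by 0.44 ± 0.07. Complement C3 stood at 0.36 ± 0.17, not past the threshold. Fibroblasts also express C1s1, Serping1 and C3, and the stellate cell and fibroblast markers were higher in the same islets (median 0.48), so these rises are not separated from that of the cell type.

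Zfp423 was 141-fold higher in knockout islets. A change of the whole chromosome neighbourhood is argued against by the 16 other tested genes within 1 Mb, whose median log2 fold change was -0.11 (SD 0.34 over genes, the highest at 0.36). The bound was first set at every value under 1 in size, which Nod2, a lower gene, missed, and was then reworded to the median because the explanation needs a rise. More stellate cells or fibroblasts are argued against by a list median of 0.48, and by a summed rise of 2319 normalized counts over the list against 3994 for Zfp423 alone. The Cre transgene, including a local effect of it on Zfp423 alone, and the loss of Ggcx cannot be told apart, since no library had Cre with intact Ggcx; Zfp423 was 2.47 times as high in knockout replicate 2 as in replicate 1, and Ggcx 2.75 times.

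Of the NF-kB list, 4 of 19 genes fell, as did the 3 clock genes above. The NF-kB list's call was lost with an estimated correlation (adjusted p = 0.618), and no test asked whether these groups moved together. A stronger isolation stress in the control islets may contribute and stays open, since the immediate early list was not called (camera adjusted p = 0.203). It was called lower without knockout replicate 2 (0.000175), while its direction was up without knockout replicate 1 (0.604) and its median was 0.022 in that fit and without control column 2. Among stress genes, Hspa1a (0.05 ± 0.08), Hspa1b (0.00 ± 0.07), Dnajb1 (0.00 ± 0.08) and Fos (0.19 ± 0.12) were not lower in knockout islets, and Hsph1 (-0.34 ± 0.07) was lower but not past the threshold. A different time of day of collection may also lower Per2 (-0.54), and cannot be told apart from genotype because the labels give no collection time. An effect of genotype stays open as well.

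The alpha, delta and PP cell lists were called higher with the preset correlation and not with an estimated one (adjusted p = 0.488 for each), and 2 of 11, 1 of 8 and 0 of 4 members passed. The delta call was lost in 3 of the 4 fits without 1 library. A lower share of beta cells would raise the markers of the other islet types alike. Their medians were 0.26 for alpha, 0.11 for delta and 0.27 for PP cells. The alpha and acinar medians lay 0.968 apart on the log2 scale, against a combined spread of 0.343 (0.470 against 0.377 without knockout replicate 1). Acinar cells belong to the exocrine pancreas, so that gap can follow how much exocrine tissue came with the islets and cannot decide this. Insulin transcripts did not take a lower share of reads, but a lower share of beta cells stays open. More alpha cells per islet may account for part of the pattern, but Gcg (0.26 ± 0.14) did not pass the threshold, and ranged from 0.13 to 0.39 with 1 library left out, which leaves this open. A change of expression within cells stays open and was not tested.

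The real grouping of the 4 libraries called 103 genes and the higher of the other 2 groupings called 0. With 1 of 3 splits giving as many genes, the splits are too few for a share under 0.05.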
